A study of Mus musculus with 8 samples.

How the data were processed

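RNA sequencing of sorted mouse Treg cells gave 8 libraries, 5 labelled chimera WT and 3 labelled chimera KO, and groups and replicate numbers were taken from the sample titles. The labels describe different mice as the source of the cells but do not tie each library to 1 animal, so p-values measure the spread between these libraries. Libraries were made from total RNA with SMART-Seq v4, a low-input, full-length kit, per the labels' protocols. That kit does not mark strand, so reads of overlapping or antisense genes cannot be told apart. The deposited table holds expected counts per gene, estimates that need not be whole. The submitters' processing notes name fastp, HISAT2, StringTie, RSEM, DESeq2 and the mm10 build, without versions or roles; the gene annotation is not given in the sources used here. Group mean columns of the authors were not used: the KO mean equalled the mean of the 3 libraries for 100% of genes, and the WT mean that of the 5 libraries for 36.85%, at a tolerance of 0.001. The table held 0 columns of other samples.

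Of 57180 genes, 51933 were found by identifier in GENCODE M21, which gave coordinates and gene types. Lengths came from the deposited table. Receptor genes, and some of the pseudogenes, were recognised from its symbols and descriptions. The other 5247 genes form a class of their own unless recognised in that way. The 28 gene lists were fixed before the data were examined, and 747 of their symbols matched directly, 18 by an older symbol and 0 not at all. Expected counts were rounded to whole numbers. In R 4.3.3, edgeR 4.0.16 was run with filterByExpr (minimum count 10), TMM factors and the quasi-likelihood test of KO minus WT on all 8 libraries without covariates, two-sided. Benjamini-Hochberg adjusted p under 0.05 counted as a call. Standard errors were computed as the absolute log2 change over the square root of the F statistic. Lists with at least 5 tested members, 25 in all, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, beside camera with an estimated correlation and fry. The medians of lists were also set against 10000 random lists of protein-coding genes matched in 20 bins of expression and 5 of length. The members of the list itself were not left out of these draws. Library measures were compared by exact two-sided permutation over the 56 splits, whose smallest p is 0.0179, with Benjamini-Hochberg adjustment over these measures. Figures were drawn with matplotlib 3.10.9.

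The genes to name were set before the data were examined. They were 7 copper genes and 6 Treg genes in every case, up to 10 genes per direction past the threshold, and, as fewer than 5 passed, 5 per direction by smallest p among genes with a mean log2 CPM of at least 3. Predicted genes, pseudogenes and receptor segments of lymphocytes were left out of that part. From each list came up to 4 members past the threshold or, where none passed, the 2 with the highest mean CPM. Some genes that this rule names are not reported here. Tnfrsf9, Rora, Id2, Cxcr3, Lef1, Tcf7, Ms4a1 and Cdc26 were singled out after their values were seen.

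The totals of 4.31 to 18.0 M (mega counts) limit low genes, and a count of 0 allows up to 3 counts; such limits cover counting error only, since the reads carry no molecular identifiers. No pair of libraries in a group agreed within sampling noise, with a chi-square per degree of freedom of at least 58.3. The procedure was tested on simulated data: 14755 genes drawn from the real means and library sizes, of which 200 were changed. At the observed dispersion edgeR recovered 0% of genes changed 2, 4, 8 or 16-fold and made 0 calls. DESeq2 recovered 2, 8, 20 and 32%, with 143 of its 174 calls false. At a dispersion of 0.1, edgeR recovered 28, 92, 98 and 94%, with 4 of 160 calls false. A 4-fold fall of the effector Treg list gave a camera adjusted p of 2.2e-05 and 0 other lists were called. Genes were simulated independently of one another, so this cannot show how often camera calls lists of correlated genes.

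The alternatives were DESeq2's size factors in edgeR, no filter, a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom with quality weights, thinning to the shallowest library, leaving out mitochondrially encoded genes and receptor segments, leaving out the 2 libraries named FY, a replicate block, and leaving out each library. Added after seeing the data were fits without WT-labelled replicates 4 and 5, without KO-labelled replicates 2 and 3, on protein-coding genes without olfactory and vomeronasal receptors, and on those genes with the length trend of each library removed.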

Results

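Gene expression was measured by RNA sequencing in regulatory T (Treg) cells, the CD4 T cells that restrain immune responses, sorted by flow cytometry from different mice. The labels put 8 libraries into 2 groups, 5 chimera WT and 3 chimera KO. They do not name the deleted gene, so the groups are called WT-labelled and KO-labelled throughout. The libraries were made with a full-length, low-input kit that does not mark strand. The deposited values are estimated counts per gene for 57180 genes. Totals in mega counts (M) were 10.6, 10.7, 11.2, 18.0 and 10.5 M in WT-labelled replicates 1 to 5, and 8.48, 4.57 and 4.31 M in KO-labelled replicates 1 to 3. Genes with at least 10 counts numbered 14090, 12758, 12826, 8250 and 9484 in the WT-labelled and 14318, 13036 and 12491 in the KO-labelled libraries. Values for single genes below are CPM after TMM scaling, that is counts scaled to a common library size (normalised CPM), as mean ± SD with n = 5 WT-labelled and n = 3 KO-labelled libraries. The TMM factors, which multiply the library sizes, were 1.15, 1.09, 1.08, 0.4 and 0.689 in WT-labelled replicates 1 to 5. They were 1.36, 1.49 and 1.32 in KO-labelled replicates 1 to 3. A factor under 1 raises the normalised CPM of a library and a factor over 1 lowers it. Positive log2 changes mean higher in KO-labelled libraries. DESeq2 values are given beside those of edgeR, but 143 of 174 DESeq2 calls were false in data simulated at the observed dispersion. Coordinates are from the GENCODE M21 annotation on the mouse GRCm38 (mm10) build.

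The series title concerns copper and the suppressive function of Treg cells, so the genes of copper handling come first. Slc31a1 (ENSMUSG00000066150), the high-affinity copper importer, stood at 1.05 ± 1.62 normalised CPM in WT-labelled and 28.9 ± 15.2 in KO-labelled libraries. Its counts were 8, 7, 1, 0 and 28 in the WT-labelled and 525, 111 and 135 in the KO-labelled libraries, so each KO-labelled library lay above each WT-labelled one. The log2 change was 4.77 (SE 1.56), with an adjusted p of 0.325 in edgeR's quasi-likelihood test over all genes and 0.0123 in DESeq2. Since the labels do not name the deleted gene, this direction neither checks the labels nor contradicts them. Slc31a1 spans positions 62360727 to 62391769 of chromosome 4 on the plus strand and overlaps the 3′ neighbour Cdc26, on the minus strand, from position 62383654, and without strand the reads of the overlap cannot be assigned to one gene. Atp7a (ENSMUSG00000033792, chromosome X, 106027276 to 106124926), a copper exporter, had 15.99 ± 15.9 in WT-labelled and 2.33 ± 0.99 in KO-labelled libraries (log2 change −2.77, SE 1.85, adjusted p = 0.451). The copper chaperone Atox1 had 282 ± 306 against 71.9 ± 21.9, and the chaperone of superoxide dismutase, Ccs, 49.4 ± 73.1 against 12.2 ± 3.78, with adjusted p of 0.367 and 0.452 in edgeR. Both WT means were raised by replicate 4, with 771 and 179, and Atox1 also stood at 393 in WT-labelled replicate 5. Without WT-labelled replicates 4 and 5 the log2 changes went from −1.97 to −0.14 for Atox1 and from −2.02 to −0.06 for Ccs. The mitochondrial copper and phosphate carrier Slc25a3 had 337 ± 157 against 204 ± 114, and Xiap 271 ± 159 against 135 ± 38.2. The exporter Atp7b and the metallothioneins were below the count filter. Atp7b had 55 and 19 counts in KO-labelled replicates 1 and 2, 1 in WT-labelled replicate 3 and 0 elsewhere. Mt1 had 338 counts in WT-labelled replicate 1, 102 in KO-labelled replicate 2 and at most 1 elsewhere, and Mt2 had 0 counts in all 8 libraries, which allows up to 3 counts in each. Among all tested protein-coding genes 31% had positive log2 changes, which is the base for the counts of signs in the lists. Of the 25 genes of the copper handling list, 16 were tested, 3 with positive and 13 with negative log2 changes. By edgeR 0 passed over all genes and 0 adjusted over the list alone, with 1 at an unadjusted p under 0.05, while DESeq2 called 1 higher and 2 lower. The list was not called against other genes (camera adjusted p = 0.401). The list of lipoylation and cuproptosis genes, copper's targets in the mitochondrial matrix, gave the same adjusted p, 0.401. Its 11 tested members included Pdha1 at 180 ± 159 in WT-labelled and 108 ± 49.5 in KO-labelled libraries.

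**Figure D1:**
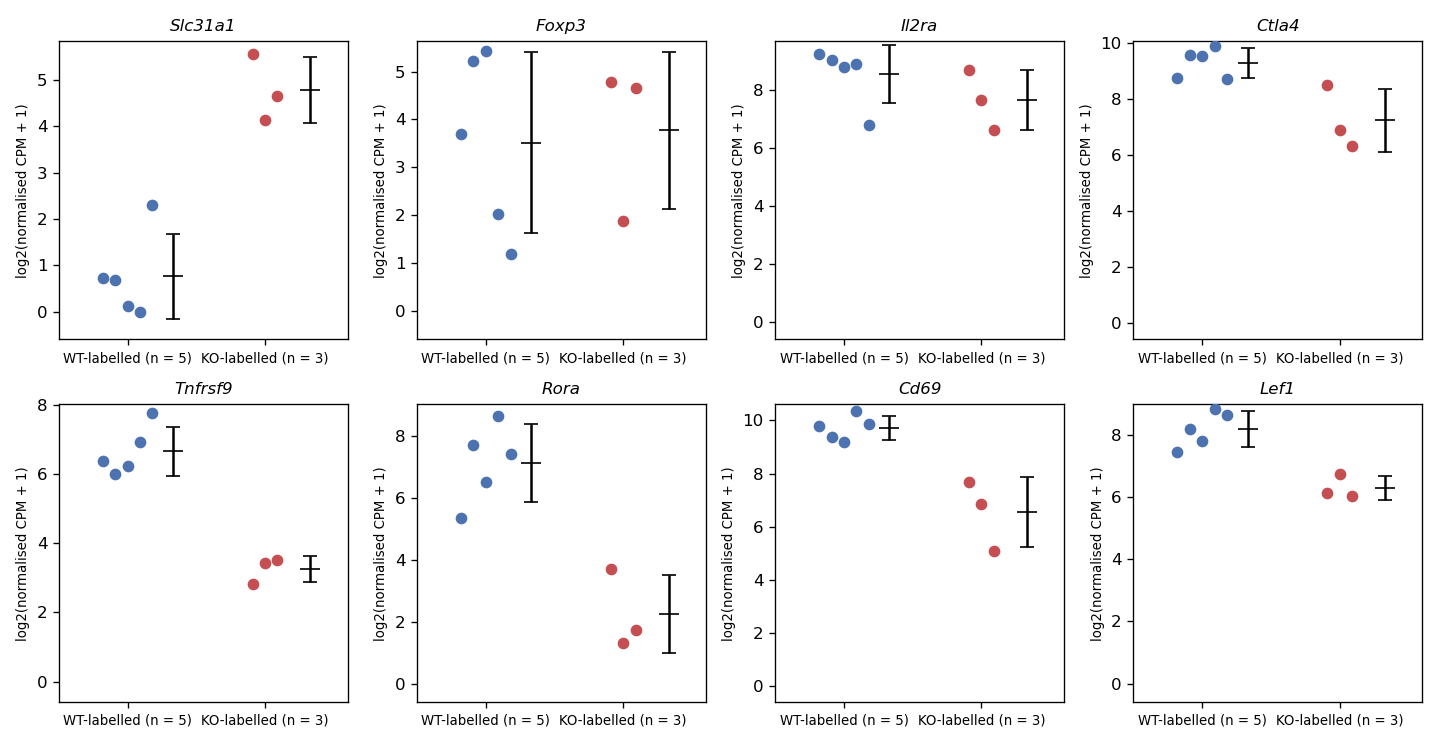
Normalised CPM, as log2 of the value plus 1, of 8 genes in each library; each point is a library, and the bars give the mean ± SD of the log2 values for 5 WT-labelled and 3 KO-labelled libraries. The groups do not overlap for Slc31a1, Ctla4, Tnfrsf9, Rora, Cd69 and Lef1, and overlap for Foxp3 and Il2ra; none of the 8 passed the adjusted test of edgeR.

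Genes that mark Treg cells were detected in both groups, at levels that varied widely between libraries. Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245), the lineage-defining transcription factor, had 19.0 ± 19.1 normalised CPM in WT-labelled and 17.8 ± 13.2 in KO-labelled libraries (log2 change −0.09, 95% interval −3.39 to 3.20). Foxp3 stood at 12.0, 36.6 and 41.9 in WT-labelled replicates 1 to 3 and at 3.09 and 1.26 in replicates 4 and 5, the libraries in which markers of B and NK cells (replicate 4) and haemoglobin genes (replicate 5) were highest. In KO-labelled replicates 1 to 3 Foxp3 stood at 26.6, 2.69 and 24.2. Low Foxp3 was thus not limited to WT-labelled replicates 4 and 5. The sign of the change turned under several settings. Il2ra, which encodes the interleukin-2 receptor alpha chain, had 428 ± 187 against 237 ± 160, and the transcription factor gene Ikzf2 (Helios) 2344 ± 1847 against 927 ± 654, with 81.0 in WT-labelled replicate 4 and 1089 to 4634 in the other WT-labelled libraries. Ctla4 (ENSMUSG00000026011, chromosome 1, 60887000 to 60915832), an inhibitory receptor used in suppression, had 657 ± 227 against 184 ± 150, each KO-labelled library lying below each WT-labelled one (log2 change −1.84, SE 0.66). Its adjusted p was 0.325 in edgeR and 0.0107 in DESeq2. Tnfrsf18 (GITR) had 494 ± 516 against 41.5 ± 54.7 (adjusted p = 0.325 in edgeR and 0.00629 in DESeq2). Il10 was below the count filter, with 220 counts in WT-labelled replicate 2, 1 in KO-labelled replicate 3 and 0 in the others. In the list of Treg identity and suppression genes, 19 of 24 tested members had negative log2 changes. By edgeR 0 passed over all genes and 0 adjusted over the list alone, with 3 at an unadjusted p under 0.05, while DESeq2 called 5 lower. The list was lower than other genes by camera (adjusted p = 0.0416), but not with an estimated correlation (adjusted p = 0.432) or among protein-coding genes alone (adjusted p = 0.301). The call was also lost without WT-labelled replicate 1 (adjusted p = 0.0736), WT-labelled replicate 2 (0.0708) or KO-labelled replicate 3 (0.0656).

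Genes of effector Treg cells, the activated subset that enters tissues, were lower in the KO-labelled libraries as a list. Of 24 tested members, 20 had negative log2 changes. The list's median was −2.46, against −0.42 over all genes and −0.95 over protein-coding genes, of which 31% had positive log2 changes. Without WT-labelled replicate 4 the list's median was −1.71, and without replicate 5 it was −1.94. The camera test gave an adjusted p of 1.55e-05. With an estimated correlation the adjusted p was 0.0514, and limma's directional fry test, which does not compare the list with other genes, gave an adjusted p of 0.00838. By edgeR 0 members passed over all genes and 4 adjusted over the list alone, with 9 at an unadjusted p under 0.05, while DESeq2 called 8 lower. The groups did not overlap for 6 of the 24 members, against 17.67% of all genes tested and 3.57% expected by chance. Of these 6, the following were chosen after their values were seen. The costimulatory receptor gene Tnfrsf9 had 111 ± 63.1 in WT-labelled and 8.74 ± 2.29 in KO-labelled libraries, the transcription factor gene Rora 180 ± 137 and 5.24 ± 5.78, and Id2 459 ± 341 and 52.9 ± 27.1. The chemokine receptor gene Cxcr3 had 119 ± 197 and 0.03 ± 0.05. The most abundant members, Lgals1 (783 ± 847 and 55.8 ± 65.6) and Cd74 (684 ± 1345 and 26.7 ± 25.6), had their highest values in WT-labelled replicate 4, at 2047 and 3088. Cd74 is also in the B cell marker list, and the B cell gene Ighm (1897) and the NK cell gene Nkg7 (2357) were likewise highest in that library; without WT-labelled replicates 4 and 5 the log2 change of Cd74 was −0.72. Without WT-labelled replicates 4 and 5 the camera adjusted p was 0.000655, and among protein-coding genes alone it was 0.000463. Against 10000 random lists of protein-coding genes matched on expression and length, the median of the list lay at percentile 0. That position was not particular to it: the B cell marker list also lay at 0 and the cell cycle list, which was not called, at 0.19.

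Genes of resting Treg cells and of the early response to T cell receptor signals were also lower as lists. In the resting list 19 of 20 members had negative log2 changes (camera adjusted p = 2.14e-05, and 0.432 with an estimated correlation). The transcription factor gene Lef1 had 307 ± 118 in WT-labelled and 79.4 ± 22.5 in KO-labelled libraries and Tcf7 385 ± 167 and 107 ± 60.3, both named after their values were seen, and among the most abundant members Ets1 had 909.7 ± 310 against 509.9 ± 169 and Bcl2 869.5 ± 383 against 559.8 ± 114. The median of this list lay at percentile 88.1 of matched lists, so it was not low against these lists, which could draw its own members. In the immediate early and T cell receptor response list 25 of 26 members had negative log2 changes (camera adjusted p = 2.17e-05, and 0.202 with an estimated correlation), 2 passed in edgeR adjusted over the list alone and the percentile was 4.48. Cd69 (ENSMUSG00000030156, chromosome 6, 129267325 to 129275436), an early activation marker, had 875 ± 281 against 119 ± 86.8 (log2 change −2.88, SE 0.70, adjusted p = 0.325 in edgeR). Tnfaip3, which restrains NF-kappaB signalling, had 673 ± 632 against 124 ± 48.0. The list of T helper cytokines and lineage factors, with 7 tested members, was not called with all libraries (camera adjusted p = 0.064, and 0.432 with an estimated correlation). It was called without WT-labelled replicate 2 (0.0195). Cd40lg had 89.9 ± 119 against 3.94 ± 6.82 and Lta 88.2 ± 91.6 against 40.9 ± 35.1.

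Genes of the respiratory chain were lower in the KO-labelled libraries as lists, and their level moved with WT-labelled replicates 4 and 5. Of 65 genes of complexes other than complex IV, 64 had negative log2 changes, with a median of −2.12, and of −1.27 without WT-labelled replicate 4 (camera adjusted p = 1.97e-10, and 0.432 with an estimated correlation). The ATP synthase gene Atp5pf had 1201 ± 1270 against 228 ± 22.4 and Atp5mg 1187 ± 1130 against 300.1 ± 55.3. Atp5pf stood at 3358 in WT-labelled replicate 4 and 1346 in replicate 5, and between 361 and 501 in the other 3. For complex IV, the copper-containing cytochrome c oxidase, 22 of 27 tested genes had negative log2 changes (camera adjusted p = 0.00107, and 0.432 with an estimated correlation), with Cox6c at 1075 ± 981 against 332 ± 118 and Cox7a2 at 776 ± 726 against 170 ± 50.3. Without WT-labelled replicates 4 and 5 the adjusted p was 0.191 for complex IV and 0.0131 for the other complexes, and among protein-coding genes alone complex IV had 0.0522. Among matched random lists, the medians lay at percentile 51.2 for complex IV, 23.9 for the other complexes and 37.7 for mitochondrially encoded genes. The random lists could draw members of these same lists. These positions thus cannot show whether the lists were low for genes of their expression and length. All 12 tested mitochondrially encoded genes had negative log2 changes (camera adjusted p = 2.14e-05, and 0.432 with an estimated correlation), and 7 passed in edgeR adjusted over the list alone. Camera called this list in 20 of 21 alternative settings, with a highest adjusted p of 0.0807. mt-Atp6 had 14863 ± 13221 against 4995 ± 2651 and mt-Co1 9737 ± 10791 against 1716 ± 1435. Of 77 ribosomal protein genes, 76 had negative log2 changes (camera adjusted p = 9.89e-07, and 0.487 with an estimated correlation); Rps19 had 3241 ± 3339 against 1433 ± 280. The adjusted camera p for this list was 0.437 without WT-labelled replicates 4 and 5. Its median lay at percentile 100 of matched lists, which could likewise draw its own members. As shares of counts, which the TMM factors do not change, ribosomal protein genes held 5.28 ± 2.24% against 4.88 ± 1.49%. Mitochondrially encoded genes held 4.31 ± 1.78% against 2.51 ± 0.924%. The size of these falls thus depends on the scaling.

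Among lists of stress and other cell functions, 2 were called. In the interferon response list 33 of 39 tested members had negative log2 changes (camera adjusted p = 0.00266, and 0.38 with an estimated correlation), with Ifi27l2a at 3098 ± 3893 against 770 ± 216 and Psmb8 at 797 ± 811 against 133 ± 61.3. Ifi27l2a stood at 9893 in WT-labelled replicate 4, and without WT-labelled replicates 4 and 5 the log2 change of Ifi27l2a went from −2.01 to −0.29 and that of Psmb8 from −2.58 to −1.18. In the heat shock and proteotoxic stress list 16 of 22 did (adjusted p = 0.0118, and 0.432 with an estimated correlation), with Hspa8 at 971 ± 905 against 184 ± 129 and Hsp90aa1 at 590 ± 323 against 148 ± 67.1. The heat shock call was absent without WT-labelled replicates 4 and 5 (adjusted p = 0.141) and without KO-labelled replicate 2 (0.0628), and neither list was called among protein-coding genes alone (0.0819 for interferon and 0.144 for heat shock, both adjusted camera p). The other lists were not called with all libraries. Adjusted camera p were 0.0736 for glycolysis and HIF targets (Gapdh 672 ± 768 against 361 ± 140, Bnip3l 558 ± 551 against 40.1 ± 11.5) and 0.0737 for antioxidant and NRF2 targets (Ftl1 1960 ± 2084 against 328 ± 158, Prdx1 1623 ± 1909 against 260 ± 91.1). WT-labelled replicate 4 had 5500 for Ftl1 and 4847 for Prdx1, and without WT-labelled replicates 4 and 5 their log2 changes went from −2.58 to −1.14 and from −2.64 to −0.80. Both lists were called with a library left out, glycolysis without WT-labelled replicate 2 (adjusted p = 0.0323) or 3 (0.0247), and antioxidant targets without WT-labelled replicate 2 (0.047) or 3 (0.0483) or KO-labelled replicate 1 (0.0485) or 2 (0.0454). With all libraries and an estimated correlation, both had an adjusted camera p of 0.442. Adjusted camera p was 0.126 for autophagy and lysosome, 0.432 with an estimated correlation, and 0.0465 without WT-labelled replicate 3 (Map1lc3b 420 ± 452 against 116 ± 95.9, Gabarapl2 397 ± 585 against 80.0 ± 18.8). It was 0.372 for cholesterol synthesis (Fdps 156 ± 247 against 1.72 ± 1.63, Msmo1 152 ± 232 against 15.4 ± 3.42). The ERK pathway, cell cycle, integrated stress response and apoptosis lists each had 0.401. Their most abundant members included Elk3 at 53.4 ± 40.4 against 17.4 ± 8.64, Map2k1 at 54.2 ± 77.1 against 15.7 ± 18.6, Atf4 at 115 ± 94.97 against 84.9 ± 17.3, Slc38a2 at 280 ± 150 against 121 ± 38.6, Mcl1 at 277 ± 161 against 171 ± 47.6 and Trp53inp1 at 311 ± 152 against 114 ± 79.8. The cell cycle list had a median log2 change of −1.96, and of 0.03 without WT-labelled replicate 5. In that list Stmn1 had 281 ± 448 against 73.5 ± 29.1, while thymidylate synthase, Tyms, had 175 ± 33.1 against 626 ± 315, each KO-labelled library lying above each WT-labelled one (log2 change 1.84, SE 0.51, adjusted p = 0.325 in edgeR). By edgeR none of these lists of stress and other functions had a member past the threshold adjusted over the list alone, while DESeq2 called members in each of them except the ERK pathway list.

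**Figure D2:**
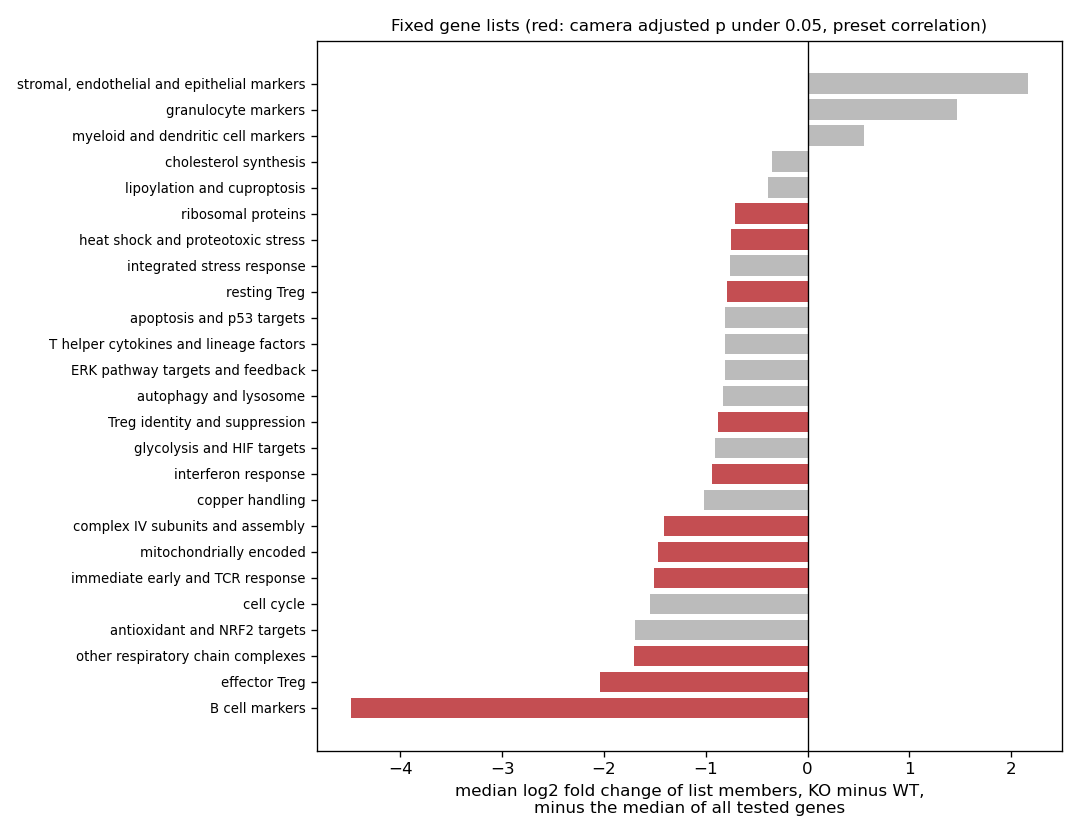
Median log2 change of the tested members of each of 25 fixed gene lists, KO-labelled minus WT-labelled, after subtraction of the median of all tested genes (−0.42); red bars mark the 11 lists with a camera adjusted p under 0.05 at a preset correlation. The effector Treg list lies at −2.04. The median of protein-coding genes was −0.95, below that of all tested genes, so a bar under 0 need not be low for protein-coding genes. No list was called with an estimated correlation.

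Markers of B cells, of CD8 T and NK cells and of erythroid cells stood highest in single WT-labelled libraries. The B cell marker list was lower in the KO-labelled libraries by camera (9 of 10 tested members negative, adjusted p = 0.0416, and 0.482 with an estimated correlation). Ms4a1 (CD20), named after its values were seen, stood at 658 normalised CPM in WT-labelled replicate 4 and at most 3.73 in the other WT-labelled libraries, and Ighm at 1897 there and 193 to 439 in the others. Its call was lost without WT-labelled replicate 4 (adjusted p = 0.598), WT-labelled replicate 3 (0.0683) or KO-labelled replicate 1 (0.106), and without WT-labelled replicates 4 and 5 together the adjusted p was 0.717. Of the CD8 T and NK cell markers, of which 4 were tested and 1 passed in edgeR adjusted over the list alone, Nkg7 stood at 2357 in WT-labelled replicate 4 and 46.2 to 118 in the other WT-labelled libraries, and Ccl5 at 1399 and 0 to 101. Of 12 erythroid and platelet markers 2 were tested; the haemoglobin genes Hba-a1 and Hbb-bs, which have near-identical copies, stood at 3569 and 3193 in WT-labelled replicate 5 and at most 2.54 in any other library. The myeloid and dendritic cell list (adjusted p = 0.451; Ctss 226 ± 122 against 159 ± 61.2, Fcer1g 132 ± 200 against 6.80 ± 11.8) had a median log2 change of 0.14 and a mean of −0.93, and the sign of the median turned with single libraries left out. The granulocyte list had an adjusted p of 0.277 (Cxcr2 24.4 ± 9.79 against 50.6 ± 25.2, S100a9 48.6 ± 81.9 against 5.74 ± 9.79). The stromal, endothelial and epithelial list had 0.0599, with positive log2 changes for 4 of 5 tested members and 1 member past edgeR's threshold adjusted over the list alone (Pecam1 87.1 ± 67.9 against 58.7 ± 2.86, Vwf 6.34 ± 2.75 against 26.1 ± 9.18). It was called higher among protein-coding genes alone (camera adjusted p = 0.0196, and 0.629 with an estimated correlation), without WT-labelled replicate 3 (0.0458) and without KO-labelled replicate 1 (0.0212). Of the sex-linked genes, 3 were tested, too few for camera; Xist had 522 ± 339 against 194 ± 204 and the Y-linked Kdm5d 10.3 ± 5.11 against 42.8 ± 19.7.

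Receptor genes of sensory neurons, pseudogenes and several classes of noncoding transcripts took a larger share of the KO-labelled libraries. Olfactory and vomeronasal receptor genes, which serve chemosensory neurons, held 0.899 ± 0.470% of the counts in the 5 WT-labelled and 4.16 ± 1.81% in the 3 KO-labelled libraries, with values of 1.28, 1.21, 1.12, 0.143 and 0.746% against 2.09, 4.95 and 5.43% (exact two-sided permutation p = 0.0179, the smallest that 56 splits allow, adjusted p = 0.0397 over the library measures). Pseudogenes held 3.89 ± 0.282% against 9.57 ± 3.59%, and antisense, sense-intronic and provisional transcripts 3.66 ± 1.68% against 9.45 ± 2.98%. Protein-coding genes held 84.5 ± 3.62% against 71.3 ± 6.75%. The total count was also lower, 12.2 ± 3.25 M against 5.79 ± 2.33 M. Each of these 4 measures gave the same exact permutation p of 0.0179. The library measures over which p was adjusted held the receptor quantity several times, also as a mean per receptor gene and as upper percentiles across receptor genes. Such repeats at the smallest p lower the adjusted p. Whether the adjusted p of 0.0397 would stay under 0.05 without them was not tested. Mitochondrially encoded genes held 4.31 ± 1.78% against 2.51 ± 0.924% (exact permutation p = 0.161), ribosomal protein genes 5.28 ± 2.24% against 4.88 ± 1.49% (0.857) and the 50 most abundant genes 19.9 ± 4.03% against 19.8 ± 2.32% (0.982). Gene by gene, 94% of the 447 tested receptor genes had positive log2 changes, with a median of 1.61, while 31% of 10321 protein-coding genes did, with a median of −0.95. Reads of receptor families and pseudogenes can be split between near-identical copies, so single members are uncertain.

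**Figure D3:**
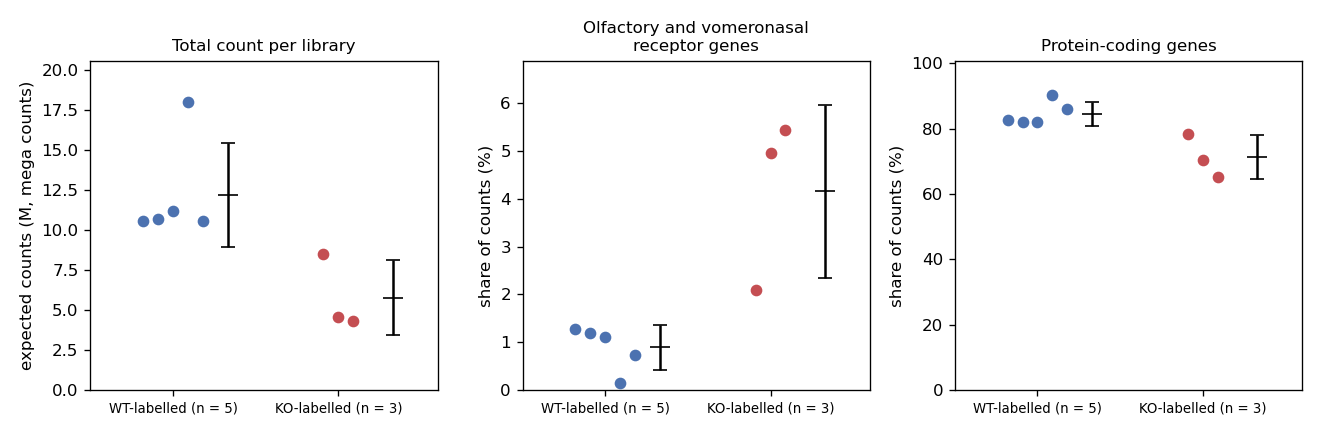
Total estimated counts (labelled in M, mega counts), and the percentage of counts in olfactory and vomeronasal receptor genes and in protein-coding genes, for each library; points are libraries and bars give the mean ± SD for 5 WT-labelled and 3 KO-labelled libraries. The receptor share is 0.143 to 1.28% in WT-labelled and 2.09 to 5.43% in KO-labelled libraries.

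Over all 14755 genes tested, edgeR called 0 higher and 0 lower at an adjusted p under 0.05, with a smallest adjusted p of 0.119. At an unadjusted p under 0.05 there were 1175 higher and 949 lower genes, DESeq2 called 945 higher and 1476 lower, and limma-voom with quality weights 18 and 4. Of the genes DESeq2 called higher, 40.1% were protein-coding, 35.1% other noncoding, 12.6% pseudogenes and 8% receptor genes, and of those it called lower 90.2% were protein-coding. The groups did not overlap for 2607 genes, or 17.67% against 3.57% by chance, with the KO-labelled libraries above for 1945 and below for 662. The genes with the smallest p that met the naming rule did not pass in edgeR. On the higher side they were the xylosyltransferase gene Gxylt2 (4.63 ± 2.74 against 178 ± 133), the receptor genes Or8s8 (0.46 ± 0.44 against 73.4 ± 22.9) and Vmn2r74 (0.95 ± 0.49 against 42.0 ± 14.3), Fam185a (0.07 ± 0.07 against 23.5 ± 31.4) and the phosphatase gene Ptprd (0.64 ± 0.44 against 22.5 ± 16.9). On the lower side they were the adhesion receptor gene Adgre5 (CD97; 294 ± 110 against 27.0 ± 19.2), the transcription factor gene Klf6 (620 ± 333 against 61.5 ± 31.4), the methionine synthase gene Mtr (43.5 ± 51.7 against 0.08 ± 0.08), Smad5 (106 ± 122 against 0.28 ± 0.27) and Smarcal1 (45.7 ± 39.5 against 0.17 ± 0.18). Adjusted p in edgeR were 0.304 to 0.325 for all 10. The spread between libraries was large, with a common dispersion of 1.671 and correlations of log2 CPM across genes of 0.525 to 0.682 within WT-labelled, 0.583 to 0.668 within KO-labelled and 0.411 to 0.704 between the groups. KO-labelled replicate 1 correlated at 0.704, 0.664 and 0.646 with WT-labelled replicates 1 to 3. With KO-labelled replicates 2 and 3 it correlated at 0.642 and 0.583. Changes are relative to the scaling: the median log2 change of all tested genes was −0.42 with TMM and −0.72 with DESeq2's size factors. With limma-voom, which used TMM factors too but weighted the libraries by quality, it was 0.18.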

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

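Most tests here were chosen after the result was seen; the exceptions are the tests of a few abundant receptor genes, of a common background profile, and of Slc31a1 against receptor genes, which were written before.

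Olfactory and vomeronasal receptor genes held a larger share of counts in every KO-labelled than in every WT-labelled library. Without the 50 receptor genes with the most counts the lowest KO-labelled share was 0.494% against at most 0.31% in WT-labelled libraries. The higher share thus does not rest on these genes alone. With them the values were 2.09% and 1.28%, so these 50 genes carried much of the share. At most 45.7% of receptor genes had a count in a KO-labelled library, at 88.1 to 116.5 counts per gene on average, which argues against genomic DNA spread evenly. Receptor gene profiles correlated between the groups (mean Spearman rho 0.754 across 807 genes, which are not independent replicates) about as within KO-labelled (0.795) and WT-labelled libraries (0.75), consistent with 1 background profile present in a larger amount. Thinning to equal depth left 2.08% against at most 1.27%, but cannot decide, since it keeps a share by construction. Lower input RNA and a biological difference between the groups were not tested and stay open.

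The effector Treg list was lower in KO-labelled libraries. It passed camera without WT-labelled replicates 4 and 5 (adjusted p = 0.000655), among protein-coding genes (0.000463) and with the length trend removed (0.00264). The range was 4.17e-06 to 0.00264 in 22 settings. The call thus did not need the libraries with fewest genes, reads outside protein-coding genes or the length trend. Passing was not particular to this list, since 4 lists were called in every setting. Among them was the resting Treg list, with a camera adjusted p of 0.00875 among protein-coding genes and a median at percentile 88.1 of matched lists. These settings cannot exclude those causes by themselves. Of the 56 splits, 1, the real one, gave a camera p as small (1.86e-06, next 7.37e-06; by fry 0.000335 and 0.0316), but this is the lowest share the splits allow and the list was taken up after it stood out among 25, so chance is not excluded. With an estimated correlation the adjusted camera p was 0.0514 over all tested genes and 0.0911 among protein-coding genes. At the preset correlation, the value without WT-labelled replicate 4 alone, which held markers of other cell types, was 3.68e-05. A lower share of effector cells or lower expression per cell may be a biological hypothesis, which was not tested.

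Slc31a1 was higher in the 3 KO-labelled libraries. Its log2 change of 4.77 was at or above that of 98.7% of 447 tested receptor genes, whose median was 1.61. The confidence interval of the Slc31a1 change, 0.96 to 8.59, takes in that median. The rank of this estimate thus cannot exclude background of the receptor kind. The largest log2 change of a tested gene within 20 kb was 0.54, in the overlapping Cdc26. That value cannot exclude reads of Cdc26, which stood at 142.5 normalised CPM in WT-labelled and 207.6 in KO-labelled libraries. Slc31a1 stood far lower, at 1.05 and 28.9, and reads of the overlap cannot be assigned without strand. Whether labels were exchanged cannot be told apart from a real difference: all 3 KO-labelled libraries lay above every WT-labelled one, but the labels do not name the deleted gene. Its edgeR adjusted p was 0.325, so a chance difference also stays open.

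For calls at an adjusted p by edgeR the splits decide nothing, since the real split has 0 genes and 0 list members, so that 56 of 56 have as many by construction (highest other 0 for both). Of the other counts, 4 of 56 splits had as many genes at an unadjusted p under 0.05 (2124, highest other 2675) and 10 of 56 as many lists (11, highest other 13), and 3 of the 24 splits run with DESeq2 had as many genes (2421, highest other 2670), so chance cannot be excluded for these. For limma-voom 2 of 56 did (22, highest other 50), a share under 0.05. Splits that set WT-labelled replicates 4 and 5 together were among those with as many genes, which points to a structure of the samples.

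Of 85 values tested, 16 had 1 WT-labelled library far from the other 4, against 4.2 by chance at 1 in 20. That expectation is only a rough guide. Many of the genes were named for a high mean CPM, which 1 extreme library can raise, and some had counts near 0. In replicate 4 the total was 18.0 M (mega counts), Nkg7 stood at 2360 normalised CPM, Hsp90aa1 at 1170, Xist at 31.2, Vwf at 1.55 and Atf4 at 0.42. In replicate 5 Hba-a1 stood at 3570, Hbb-bs at 3190, Bcl2 at 232, Il2ra at 111 and Slc38a2 at 53.4. Il10 stood at 19.1 and Elk3 at 0.61 in replicate 2, Mt1 at 28.0 in replicate 1, and Ptprd at 1.43 and Atp7b at 0.08, a single count, in replicate 3.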

How the results depend on the processing

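The fits without WT-labelled replicates 4 and 5, without KO-labelled replicates 2 and 3, on protein-coding genes, and with the length trend removed were chosen after seeing the data. Deviations from the group means correlated at r of 0.059, 0.009 and 0.035 for libraries with the same replicate number. For different numbers r was −0.044 to 0.011. All were near 0, so the numbers show no clear pairing, but this check cannot exclude one. Where no reason is given, the cause was not tested. edgeR's 0 higher genes became 1 without a filter, 1 at a mean of at least 5 CPM, 945 with DESeq2 and 18 with limma-voom; its 0 lower genes became 1476 and 4 with these tools, and its 0 list members 147 with DESeq2. The 11 lists became 7 under the replicate block, 7 on replicates 1 to 3 without it, 7 without WT-labelled replicates 4 and 5, 7 on protein-coding genes, 5 with the length trend also removed, 0 with an estimated correlation, 1 by fry and 2 by mixed fry, and 10 to 14 with a library left out. Without the FY libraries or without WT-labelled replicates 4 and 5, the total differed by −7.25 and −5.02 M (−6.40 M with all; M, mega counts) and the receptor share by 3.43 and 2.95 points (3.26 with all), each with an exact permutation p of 0.1, the smallest that 3 against 3 allows. With a library left out these were −7.75 to −4.96 M and 2.62 to 4.29 points.

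Signs of log2 changes turned for genes that passed no edgeR test. Foxp3 gave 0.10 at 5 CPM, 0.21 thinned, 1.90 without FY, 0.40 without KO-labelled replicates 2 and 3, 0.26 on protein-coding genes, 0.086 with length removed and −0.58 to 0.45 with a library left out. With limma-voom Gabarapl2 gave 0.63, Stmn1 0.067, Map2k1 0.16, Gapdh 0.37, S100a9 0.65, Atf4 0.007 and Pdha1 0.17. Under the replicate block Ccs gave 0.24, Gabarapl2 1.06, Stmn1 0.44, Map2k1 0.42, Gapdh 0.77 and Pdha1 0.73. On replicates 1 to 3, which is also the fit without WT-labelled replicates 4 and 5, Gabarapl2 gave 0.038, Stmn1 0.18, Gapdh 0.84 and Pdha1 0.62. Gapdh gave 0.078 with length removed and −1.27 to 0.065 with a library left out, and Atf4 0.084 on protein-coding genes and −0.75 to 0.13. Without FY, Ctss gave 0.015 and Pecam1 0.23. The ribosomal list gave 0.90 with length removed. Of the other values for single genes and lists, 1938 kept direction and side of the threshold, 56 came past it and 39 no longer passed. Totals as low as 4.31 M limit genes with few counts.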

Other observations

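The pathway names of the deposited table were tested after the other results were seen, with camera on protein-coding genes at a preset correlation. Of 321 pathways 28 had an adjusted p under 0.05, 24 lower and 4 higher in KO-labelled libraries, against 0 with an estimated correlation and 0 with fry. Among the lower ones were oxidative phosphorylation (adjusted p = 1.09e-06), the spliceosome (5.09e-05), the proteasome (0.000224) and T cell receptor signalling (0.00727), and among the higher ones neuroactive ligand-receptor interaction (0.025). The first overlaps the fixed respiratory lists.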
